A study of Mus musculus with 5 samples.

How the data were processed

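Nucleosome signal around transcription start sites (TSSs) was derived from ATAC-seq, an assay in which the Tn5 transposase inserts sequencing adapters into accessible DNA so that fragment ends and fragment lengths report open DNA and the nucleosomes beside it. Per the labels, the cells were mouse pre-B cell acute lymphoblastic leukaemia cells of C57BL/6J strain, transformed with BCR-ABL1, a constitutively active tyrosine kinase fusion, and lacking p19 (p19Arf, a tumour suppressor encoded at Cdkn2a). Of the 5 libraries, 2 came from cells with wild-type PHF6 (replicates 1 and 3) and 3 from PHF6 knockout cells (replicates 1, 2 and 3). PHF6 is a nuclear and nucleolar protein with zinc-binding domains of the plant homeodomain type. The design text calls the replicates biological, and no source used here says whether they were separate cultures, clones or animals, so the p-values measure the spread between these libraries only. Per the labels' protocols, nuclei were lysed and transposed with a Nextera kit.

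The submitters' processing notes name Bowtie2, MACS2 and the mouse genome build mm9, with no versions. The deposited values are a nucleosome signal per bin, and the file names attribute them to NucleoATAC, a program that estimates nucleosome positions from ATAC-seq fragments. NucleoATAC's version and settings, the track that was used and the list of TSSs are not given in the sources used here. The authors deposited for each library a matrix of signal with 37310 rows and 200 columns, and no header or row name. Each row covers 1000 bp on either side of a TSS in bins of 10 bp. All values were 0 or higher, and none was missing. How the authors scaled the deposited signal between libraries is not given in the sources used here. The files hold no read counts, so the depth behind each value is unknown and no counting interval can be given. Over all deposited rows, the mean deposited signal was 0.533 and 0.538 in the wild-type libraries (replicates 1 and 3), and 0.600, 0.559 and 0.316 in knockout replicates 1, 2 and 3.

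The rows carry no gene name, identifier, coordinate or strand. No gene was therefore named, no gene was inferred from the place of a row, and the 14 gene lists chosen in advance could not be tested. The unit of analysis was the TSS window, not the gene. A window is cited below by its row number, which is the same in all 5 files. Of the 37310 rows, 818 had no signal in any library and 45 repeated another row in all 5 libraries; the remaining 36447 distinct windows were analysed.

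Whether the columns follow the direction of transcription was tested on the values. Windows of neighbouring TSSs overlap, and where their bins coincide they hold identical runs of signal, either in the same or in reversed column order. Among bins with signal above 0.01 in both wild-type libraries, 405 pairs of windows (789 windows) shared such runs in the same order and 0 pairs in reversed order, which allows a share of up to 0.741% reversed pairs (3 counts of the total; counting error only). The columns thus follow 1 fixed orientation for all windows, and upstream cannot be told from downstream. The region planned as the +1 nucleosome (+50 to 200 bp) holds the +1 nucleosome of some genes and the nucleosome upstream of the TSS of others, and is called the right flank here. The region planned as nucleosome-depleted (-150 to 0 bp) covers the left slope of the profile. Orientation-free regions were added after this was seen. They were a central trough within 50 bp of the TSS, both flanks at 50 to 200 bp, and outer parts at 700 to 1000 bp. Because windows overlap, counts of windows are not counts of genes.

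Each library's signal was divided by its mean over all distinct windows and bins, giving a relative signal with a mean of 1. Per window, the mean relative signal over a region was taken as log2(value + 0.1), and knockout was compared with wild type in limma 3.58.1 (R 4.3.3; lmFit and eBayes with a trend on mean signal; two-sided; Benjamini-Hochberg adjustment over all windows tested; threshold 0.05). A fold change on the log2(value + 0.1) scale understates changes at windows of low signal. Contrasts between regions were differences of the log2 values. Average profiles were summarised per library in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and compared by an exact two-sided permutation test of the difference in means over the 10 splits of the libraries into 2 and 3. The smallest p this permutation test can give with 2 against 3 libraries is 0.1, so no single-value comparison could pass 0.05 in it. Benjamini-Hochberg values were computed over the 35 profile comparisons made on all, high-signal and low-signal windows. High-signal windows were the 25% with the highest relative signal averaged over all 5 libraries (9112 windows), and low-signal windows the lower 50% (18224 windows); both classes were defined after the data were seen. The rule for single windows, fixed before the data were examined, took those with an adjusted p under 0.05, or failing that those with the smallest unadjusted p; with no names to print, the leading 2 per direction are given.

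The limma step was tested on simulated data drawn from the observed window means and residual spread, with 100 windows changed at each size. Rises and falls were both simulated with normal noise and no lower limit, so large falls could pass below the lowest possible value. The recovered shares are therefore approximate. For the whole window, 0% of the 2-fold changes (log2 1) and 21% of the 8-fold changes (log2 3) were recovered among 36447 windows. The shares were 4% and 91% among the 9112 high-signal windows, and 0% and 34% among 27335 windows without the 25% of lowest mean. For the right flank among 36447 windows the shares were 1% and 2%. Each window's residual spread, estimated from 5 libraries, was taken as its true spread, so the simulated spreads differ more between windows than true spreads would. The recovered shares may therefore be too low. In this simulation the planned fits over all windows missed most changes of these sizes. The share that the fits to the real data miss is not known. Other settings tried were no scaling, quantile normalization, a pseudocount of 0.5, leaving out the 25% of windows with the lowest mean, other region limits, a replicate block, a fit without the trend and leaving out each library. Scaling without the top 1% of windows, all deposited rows, high-signal windows alone, and window classes by a mean that weights the genotypes equally or leaves out the libraries measured were added after the data were seen. No bin was missing from any library and no window could be assigned to a gene, so other treatments of missing bins and of several TSSs per gene did not apply.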

Results

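ATAC-seq nucleosome signal was compared between BCR-ABL1-transformed, p19-null mouse pre-B leukaemia cells with and without PHF6, over 36447 distinct TSS windows in 2 wild-type and 3 knockout libraries. The libraries differed in level and in how many bins held signal. In these windows, bins at exactly 0 made up 47% and 44.5% of the wild-type libraries (replicates 1 and 3), and 45.2%, 52.8% and 65.4% of knockout replicates 1, 2 and 3. Knockout replicate 3 also had the lowest mean deposited signal (0.323, against 0.545 to 0.614 in the other libraries) and no signal at all in 1662 of the windows, against 323 to 542 in the others. The data carry no gene names, so the B-cell identity genes that the title of the series refers to could not be examined one by one, and the Phf6 promoter could not be located as a check on the labels.

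The first comparison asked whether the average arrangement of nucleosomes around the TSS differed without PHF6. In both genotypes the profile had a form known from promoters: a trough of low nucleosome signal at the TSS, a strong maximum on either side, and weaker maxima further out. The right-hand maximum lay at 135 bp in all 5 libraries. The left-hand maximum lay at -145 bp in 4 libraries and at -135 bp in wild-type replicate 3. After the profile was folded about the TSS, the first maximum lay at 135 bp and the next at 315 bp in each library over all windows. In the high-signal windows the next folded maximum lay at 315 bp in the 3 knockout libraries and at 325 bp in wild-type replicate 1, and none was found in wild-type replicate 3. In the windows of middle signal the right-hand maximum lay at 125 bp in knockout replicates 2 and 3 and at 135 bp in the other 3 libraries (exact permutation p = 0.4).

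Relative signal at the right-hand maximum was 1.92 ± 0.0791 (SD, n = 2) in wild-type and 2.23 ± 0.112 (SD, n = 3) in knockout libraries. The lowest point of the central trough was 1.01 ± 0.0686 (SD, n = 2) in wild type and 0.790 ± 0.0685 (SD, n = 3) in knockout. The distance from trough to maximum was 0.909 ± 0.148 in wild type and 1.44 ± 0.175 in knockout. Each of the 3 knockout libraries lay beyond both wild-type libraries for these 3 measures, and each gave an exact permutation p of 0.1, the smallest that 2 against 3 libraries allow (adjusted p 0.269 over 35 comparisons). Without scaling, the difference in height at the right-hand maximum was 0.0676 and the exact permutation p was 1; knockout replicate 3 was at 0.720 there, below both wild-type libraries (1.08 and 1.02). The unscaled distance from trough to maximum differed by 0.225 in place of 0.526, with knockout replicate 3 (0.452) between the wild-type libraries (0.552 and 0.443; exact permutation p = 0.3). The unscaled central minimum differed by -0.157 (exact permutation p = 0.2).

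**Figure D1:**
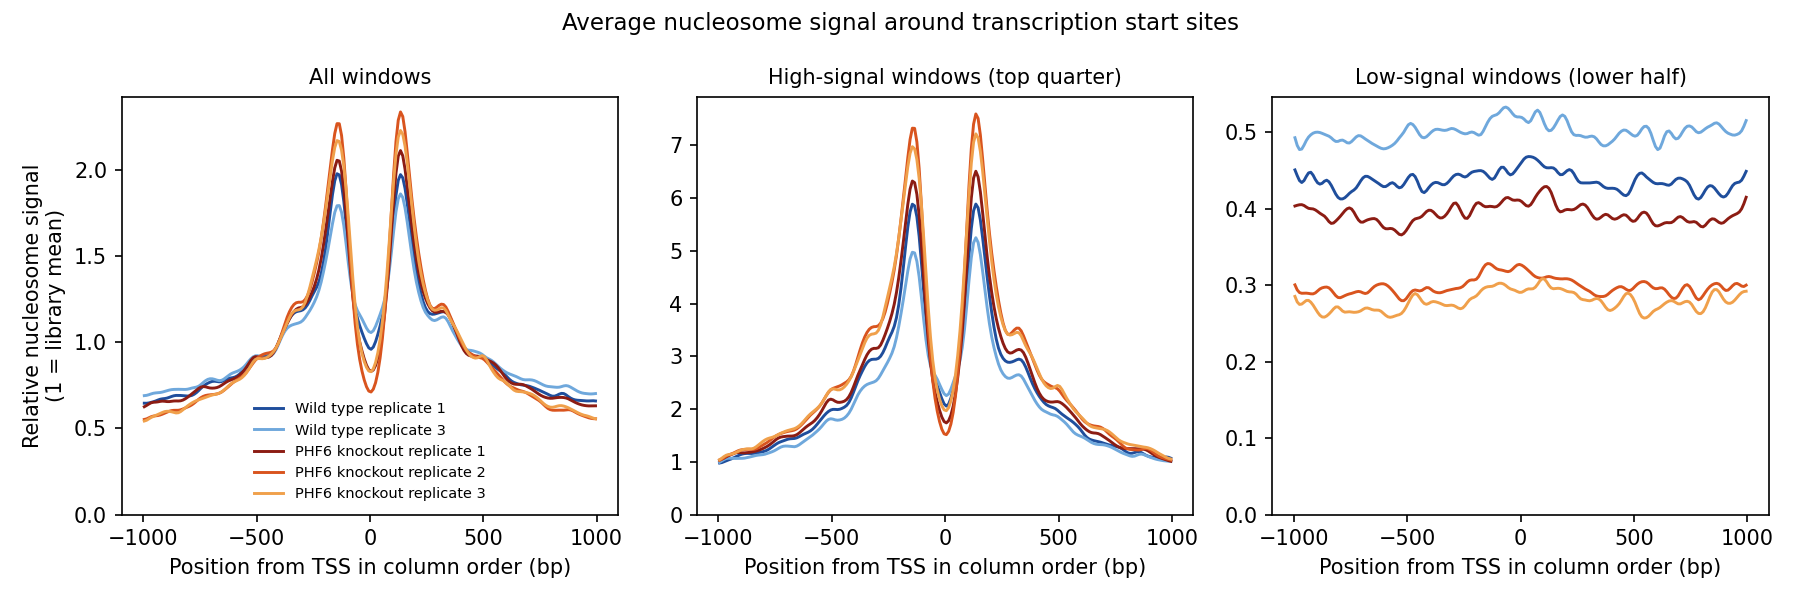
Average relative nucleosome signal (library mean = 1) against position from the TSS in bp, in the fixed column order of the deposited data, for all windows, the 25% of highest signal and the 50% of lowest signal; each line is a library. The 3 knockout libraries have higher maxima at 135 bp and a lower central minimum (0.711 to 0.831) than the 2 wild-type libraries (0.959 and 1.06) over all windows, and low-signal windows are nearly flat.

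The flanks and the trough differed in unlike ways between windows of strong and weak signal. The knockout to wild-type ratio of relative signal at the flanks was 1.24 in the 9112 high-signal windows, 0.941 in the 9111 windows of middle signal and 0.706 in the 18224 low-signal windows. At the central trough it was below 1 in each of these classes, at 0.848, 0.843 and 0.699. In the high-signal windows the flanks had a relative signal of 4.37 ± 0.377 (SD, n = 2) in wild type and 5.44 ± 0.405 (SD, n = 3) in knockout. The central trough had 2.37 ± 0.103 in wild type and 2.01 ± 0.215 in knockout. The exact permutation p was 0.2 for the flanks and 0.2 for the trough. The flank to trough ratio of the average high-signal window was 2.02 and 1.68 in the wild-type libraries and 2.51, 3.16 and 2.53 in knockout replicates 1, 2 and 3 (exact permutation p = 0.1, adjusted p = 0.269). This ratio needs no scaling between libraries. As deposited, the central trough of these windows was 1.25 and 1.34 in wild type and 1.21, 1.03 and 0.721 in knockout, while the flanks overlapped between genotypes (2.53 and 2.26 against 3.05, 3.26 and 1.82). The median log2 difference per window was 0.65 for the contrast of flanks and trough and -0.41 for the trough; quantile normalization, which gives each library the same distribution and so sets the median near 0, left -0.09 and 0.11. The share of high-signal windows whose trough held less than 0.5 of the flank signal was 61.7% ± 2.94 (SD, n = 2) in wild type and 71.2% ± 2.66 (SD, n = 3) in knockout, with all 3 knockout libraries above both wild-type libraries (exact permutation p = 0.1). High-signal windows with a trough at exactly 0 made up 6.12% and 4.74% in wild type and 7.93%, 14.6% and 11.4% in knockout replicates 1, 2 and 3 (exact permutation p = 0.2). Knockout replicates 2 and 3 were also the libraries with the most bins at 0. The median distance between the strongest bins within 400 bp to the left and right of the TSS was 355 bp ± 7.07 in wild type and 367 bp ± 5.77 in knockout, and wild-type replicate 1 and knockout replicate 1 had the same median (exact permutation p = 0.3).

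The 18224 low-signal windows had nearly flat average profiles in both genotypes. Their flank to trough ratio was 0.989 ± 0.00665 (SD, n = 2) in wild type and 0.999 ± 0.0201 (SD, n = 3) in knockout (exact permutation p = 0.5). Their relative signal was 0.469 ± 0.0450 in wild type and 0.324 ± 0.0612 in knockout (exact permutation p = 0.2). The mean of the high-signal windows divided by that of the low-signal windows was 5.26 and 4.20 in the wild-type libraries and 6.18, 9.01 and 9.70 in knockout replicates 1, 2 and 3 (exact permutation p = 0.2). Each knockout library lay above both wild-type libraries. When the windows were ranked in 8 groups by mean signal, the knockout to wild-type ratio of relative signal was 0.680 in the lowest group, 0.934 in the group ranked 6 and 1.24 in the highest (exact permutation p 0.2, 0.1 and 0.2). The ranking used a mean in which 3 of the 5 libraries were knockout. With the genotypes weighted equally the ratios were 0.748, 0.918 and 1.23. When windows were ranked on 1 wild-type and 1 knockout library and measured in the others, the 6 such rankings gave 0.578 to 0.809, 0.918 to 0.952 and 1.16 to 1.33. Because each library was scaled to a mean of 1, a lower share in some windows comes with a higher share in others.

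**Figure D2:**
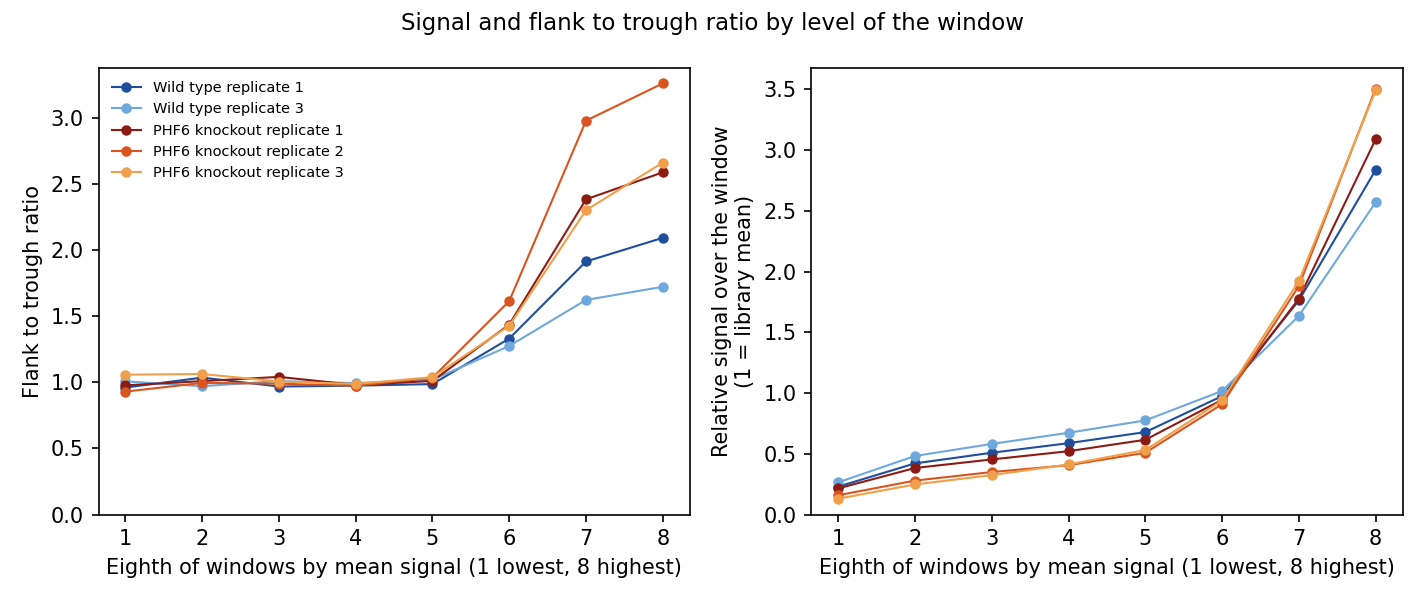
Flank to trough ratio (left) and relative signal over the window (right, library mean = 1) in 8 equal groups of windows ranked by mean signal over all libraries; each point is a library. Flank to trough ratios of the libraries lie close to 1 in the 5 lowest groups and part by genotype in the highest, from 1.72 and 2.09 in wild type to 2.59, 2.66 and 3.26 in knockout.

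The second comparison asked which individual windows differed. Over all 36447 windows, no window passed an adjusted p of 0.05 in limma for the whole window, the right flank, the planned depleted region, or the contrast of those regions. At an unadjusted p under 0.05 there were 4089 windows for the whole window, 2871 for the right flank, 2805 for the planned depleted region and 2833 for the contrast. The added central trough and flank to trough contrast also gave 0 windows (2544 and 2946 at an unadjusted p under 0.05). The wild-type and knockout libraries did not overlap in 30.1% of windows, where interchangeable libraries would give 20% on average. All windows share the same 5 libraries, so a shift of whole libraries moves this share. Its spread over other splits of the libraries was not computed. The median log2 difference over all windows was -0.21 for the whole window, -0.29 without scaling and -0.0052 after quantile normalization.

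The windows with the smallest p in each direction differed several-fold. They were picked by p from the same data, so the sizes of their differences may be overstated. The window in row 35830 had a relative signal of 1.4 ± 0.0649 (SD, n = 2) in wild type and 4.98 ± 0.695 (SD, n = 3) in knockout, a log2 difference of 1.75 (SE 0.27; limma adjusted p = 0.115). The window in row 16401 had 1.55 ± 0.0208 in wild type and 5.0 ± 0.329 in knockout (limma adjusted p = 0.115). In the other direction, the window in row 37014 had 3.75 ± 0.806 in wild type and 1.01 ± 0.167 in knockout (limma adjusted p = 0.126), and the window in row 10548 had 3.13 ± 0.476 and 0.908 ± 0.350 (limma adjusted p = 0.141). None of these passed the threshold over all windows in the main fit. After quantile normalization all 4 passed over all windows, the largest of their limma adjusted p-values being 0.0268. With a pseudocount of 0.5, all but the window in row 10548 passed (limma adjusted p = 0.066 for that window). All 4 also passed when the 25% of windows with the lowest mean were left out. The largest of their limma adjusted p-values was then 0.00437. Over the settings run for these 4 windows their limma adjusted p-values ranged from 0.000236 to 0.855, and no direction changed in those settings.

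Leaving out that 25%, a setting chosen in advance, gave 179 windows past the threshold, of which 154 rose and 25 fell in knockout (27335 tested). Of these 179 windows, 159 were high-signal windows. A fit to the 9112 high-signal windows alone, chosen after the data were seen, gave 341 windows, of which 331 rose and 10 fell, against a median log2 difference of 0.21 over the high-signal windows. With quantile normalization, which removes that common shift, 46 high-signal windows passed, 28 of them higher and 18 lower; 37 were among the 341. A mean over 3 knockout and 2 wild-type libraries lets windows that are higher in knockout into the set more easily; with the genotypes weighted equally, 337 windows passed, 326 of them higher and 11 lower. The 331 windows that rose had a relative signal of 2.10 ± 0.172 (SD, n = 2) in wild type and 4.56 ± 0.514 (SD, n = 3) in knockout, and the 10 that fell 3.86 ± 0.103 and 1.57 ± 0.0469; these values describe windows selected on the same data. The counts depended on single libraries: without knockout replicate 2, 341 became 15 and 179 became 22. Without knockout replicate 3 they became 218 and 182, and without knockout replicate 1 they became 371 and 202. Both counts were also lower without either wild-type library, but such fits leave 1 wild-type library with no spread of its own. The median log2 difference of 0.21 over the high-signal windows was then 0.26 without wild-type replicate 1 and 0.14 without wild-type replicate 3.

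The third comparison asked whether libraries of 1 genotype resembled each other more than those of the other. Across windows, which are not independent replicates, Spearman's rho of the whole-window signal was 0.749 to 0.778 between knockout libraries, 0.737 between the wild-type libraries and 0.711 to 0.741 between genotypes. Within the high-signal windows the corresponding values were 0.585 to 0.663, 0.559 and 0.427 to 0.542, so every pair within a genotype exceeded every pair between genotypes there. For the shape of the signal inside a window, the wild-type pair did not exceed the pairs between genotypes. The median Pearson correlation over the 200 bins of a high-signal window was 0.507 between the wild-type libraries, within the range of 0.454 to 0.574 between genotypes, and 0.561 to 0.654 between knockout libraries. The strongest right-hand bin lay within 20 bp in 45.4% of high-signal windows between the wild-type libraries, in 40.6% to 48.8% between genotypes and in 46.9% to 54.8% between knockout libraries.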

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

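The central trough, the flank to trough measures, all deposited rows, equal weights, scaling without the top 1% of windows and high-signal windows alone were chosen after the data were seen. The count of 0 for the whole window became 12 with quantile normalization, 7 with a pseudocount of 0.5, 179 without the 25% of windows of lowest mean, 15 with all deposited rows (all 15 lower in knockout), 341 with high-signal windows only and 46 with those windows after quantile normalization. With genotypes weighted equally in the choice of windows, 179 became 174 and 341 became 337. The last 6 settings change which windows are tested, and limma's trend and spread were estimated anew on those windows. The window in row 35830 kept its log2 difference of 1.75 without the 25% of lowest mean. Its limma adjusted p went from 0.115 to 0.000241. The count moved under quantile normalization, the pseudocount and these 6 settings for reasons that were not tested. It stayed 0 under the other settings and without any 1 library (0 to 0). For the other per-window regions and contrasts, the count was 0 under every setting except where a wild-type library was left out. Leaving out 1 library gave 0 to 2709 for the right flank, 0 to 2633 for the planned depleted region and 0 to 3735 for the central trough. The high counts came without wild-type replicate 1 (2709, 2633 and 3735) and without wild-type replicate 3 (2371, 2261 and 3236), fits in which the lone wild-type library is assumed to vary like the knockout libraries; 1223 of the 2709, 1158 of the 2633 and 1613 of the 3735 were windows with all 3 knockout libraries at 0 and so no spread. Both contrasts gave 0 to 0.

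Deviations from the group means gave no sign that the shared replicate numbers pair the libraries. They correlated at -0.06 between wild type and knockout replicate 1 and at -0.04 for replicate 3. With the replicate block the count over all windows was 0 in each fit, and it was 65 in place of 179 and 35 in place of 341. The difference in the height of the right-hand maximum (0.309) ranged from 0.253 to 0.366 without 1 library, that of the central minimum (-0.217) from -0.266 to -0.169, their distance (0.526, and 0.225 unscaled) from 0.422 to 0.631, the position of the maximum (0 bp) from 0 to 0, and the log2 flank to trough ratio (0.557) from 0.425 to 0.690; the other definitions of this ratio gave 0.558 to 0.652. Mean correlations moved with Pearson's r in place of Spearman's rho from 0.729 to 0.775 between genotypes, from 0.763 to 0.814 within knockout and from 0.737 to 0.785 within wild type. The 4 named windows and the average profile differences above kept their direction under the settings run for them. Quantile normalization sets medians near 0, so it does not test the direction of the trough or the contrast. Tests of 14 gene lists and of several TSSs per gene were not run, because no names are given, and no bin was missing. The depth is unknown. Bins at 0 made up 44% to 65% of the libraries, and whether they limit the fits over short regions was not tested.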

Other observations

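The tests of called windows, of the flank to trough ratio and of other splits of the libraries were chosen after the results were seen. In the 331 high-signal windows that rose in knockout, the knockout to wild-type ratio was 2.00 at the trough, 2.39 at the flanks and 1.75 in the outer parts, and the flank to trough ratio was 2.26 ± 0.206 (SD, n = 2) in wild type and 2.70 ± 0.304 (SD, n = 3) in knockout, with wild-type replicate 1 at 2.40 and knockout replicate 1 at 2.42. In the 8771 high-signal windows without a call, the knockout to wild-type ratio was 1.20 at the flanks and 0.813 at the trough. The 331 windows were selected on a total that includes the trough, so these values do not test for a difference in shape. Without quantile normalization 331 of the 341 called windows were higher; with it 28 of 46 were.

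A pair of windows stood far above the others in every library. The window in row 22298 had a mean deposited signal of 62.3 and 60.4 in wild-type replicates 1 and 3, and 71.6, 52.5 and 44.8 in knockout replicates 1, 2 and 3. The window in row 20025 had 25.1, 24.8, 29.6, 28.2 and 19 in the same order. The next window in rank, row 10340, had 4.53, 4.32, 5.33, 6.90 and 3.17.

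The flank to trough ratio of the average high-signal window was higher in each knockout library than in both wild-type libraries, by 0.56 on the log2 scale. An even background of signal in the wild-type libraries could fill the trough, but subtracting each library's mean over the low-signal windows left the difference at 0.572 (SE 0.185), which argues against it. The mean signal level of a library is argued against as well, because both wild-type levels lay inside the range of the knockout libraries while the lowest knockout and the highest wild-type log2 ratio were 0.312 apart, more than the larger group SD of 0.188. Differences between libraries in transposition or enrichment, unrelated to PHF6, stay open and cannot be told apart from genotype: the exact permutation p is 0.1, the least that 10 splits allow, and no fragment lengths or read counts are in the tables. An effect of PHF6 on this ratio remains a hypothesis. For the trough alone in these windows, the exact permutation p was 0.2, and limma called 0 windows (875 at an unadjusted p under 0.05).

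Among the 9112 high-signal windows the split by genotype gave 341 windows past the threshold, and the highest count among the other splits was 0. Of the 10 splits, 1 gave as many, the real one; 10 splits are too few for a share under 0.05. Among the 27335 windows left without the 25% of lowest mean, the split by genotype gave 179; the split that sets knockout replicates 2 and 3 apart gave 19, another gave 1 and the others 0. Over all 36447 windows the real split gave 4089 windows at an unadjusted limma p under 0.05. The split that sets knockout replicates 2 and 3 apart from the other 3 libraries gave 5139. Without the 25% of lowest mean these counts were 3457 and 3912, and among the high-signal windows 1621 and 1379. That split keeps both wild-type libraries together and moves only knockout replicate 1, so it partly follows genotype. Knockout replicates 2 and 3 were also the libraries with the most bins at 0 (52.8% and 65.4%). These counts may reflect a structure of the libraries that is not genotype alone, but this was not tested.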
